A study of Mus musculus with 496 samples.

How the data were processed

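The assay for transposase-accessible chromatin (ATAC-seq) was read in 496 libraries of sorted mouse spleen cells, per the labels: macrophages (217 libraries), CD8 T cells (223), B cells (24), NK cells (23) and dendritic cells (9). The mice were wild type or carried 1 of 12 mutations of the JAK-STAT pathway, which relays cytokine signals from surface receptors to the nucleus. Cells were processed straight after sorting (homeostatic) or after 20 h in culture, in culture either untreated, with interferon beta (IFN-beta, 1000 U/ml) for the last 1.5 h, or with IFN-beta for the whole 20 h. The labels name 69 batches, each made by 1 of 6 research groups, whose codes (BS, MM, RM, SK, TD and VS) are used as the labels give them.

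The authors trimmed reads with Trimmomatic 0.32, aligned them to mm10 with Bowtie2 2.2.4, called peaks with MACS2 2.7.6 and worked in R 3.6.1, per the submitters' processing notes. The deposited values are raw counts of reads over a common set of 277237 regions, whole numbers without normalization. Totals per library ranged from 415419 to 13409297 with a median of 2842114. Every count column was used. Region starts in the deposited table count from 0 and are given here from 1, and all chromosome ends fit the GRCm38 (mm10) reference. Intervals and floors from counts cover counting error only, since the reads carry no molecular identifiers.

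Regions were linked to the gene with the nearest GENCODE M21 transcription start within 50 kb, protein-coding genes first, which gave a gene to 241830 regions. A region within 1 kb of a start of the gene it is named for is called a promoter region. A gene named for a region is only its nearest, so that a region may act on another gene. Reads that align to near-identical copies, as in the Oas, Ifi27, Trim30, Gbp and T cell receptor families, could be shared between copies.

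Groups were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg over the regions tested), and a region was called at an adjusted p under 0.05. All adjusted p-values of single regions come from this test unless another is named. All genotypes of a cell type shared 1 estimate of the spread. Each mutant was compared with wild types of its own research group, with the batch as a covariate. A mutant library whose batch held no wild type of that cell type therefore added nothing to a comparison, and wild types of batches without the mutant added little beyond the spread. The numbers of libraries given are all those of the 2 groups. Culture was compared with the homeostatic state in wild types with the research group as covariate. The IFN-beta response of wild types (treated against untreated) used the batch as covariate. The difference between the response of a mutant and that of wild types pooled over all research groups was tested as an interaction, as the mean of the 1.5 h and 20 h responses. The same test on the own research group alone was fixed beforehand as a second reading.

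The batch is the replicate block, since the labels give mutant and wild type libraries the same batch. Over 112 batch pairs of homeostatic libraries, 66 had deviations from their group means that correlated above 0.1 across regions, and in 10 of 32 comparisons every pair did.

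Regions named in the text were chosen by a rule fixed before the data were examined: for a homeostatic comparison, the 5 largest increases and 5 largest decreases among called regions with a mean of at least 1 CPM (counts scaled to the size of the library), the same direction in every batch pair and a distance over 10 Mb from the mutated gene, 1 region per gene. For culture and IFN-beta in wild types the 12 largest in each direction were taken, for mutant responses 5, and for contrasts of alleles 3. Few of these are printed, and those without a named gene nearby were passed over. The targeted gene and examples of each gene list were taken as well.

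Also fixed beforehand were 15 gene lists: interferon-stimulated genes (54 genes), guanylate-binding and immunity-related GTPases, MHC class I presentation, MHC class II presentation, cytokine feedback and STAT5 targets, effector CD8 T cell genes, naive T cell genes, inhibitory receptors, red pulp macrophage identity, inflammatory cytokines and chemokines, alternative activation, immediate early and stress genes, cell cycle, cholesterol and lipid genes, and JAK-STAT components. Marker lists covered 10 cell types. A list was tested through the regions within 10 kb of a start of its genes with limma's camera (preset correlation 0.01, and an estimated correlation) on log2 CPM with a prior count of 2, adjusted over lists and comparisons of a family. The regions called in wild type CD8 T cells with a log2 change above 1 at either time formed the set of interferon-responsive regions (105 regions), tested with camera and with fry, which asks whether the set moves on balance in 1 direction. This set was chosen on these libraries, so that the sizes of wild type responses over it are not independent of the choice. Its use in macrophages, in which no region was called, and its test against the own research group were chosen after seeing the data.

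Motifs were matched as fixed consensus strings on either strand and compared between called and other tested regions with Fisher's exact test (two-sided, adjusted over all motif tests). The motifs were ISRE (bound by STAT1-STAT2-IRF9), GAS (bound by STAT dimers), AP-1, PU.1 and CTCF. Regions are not independent replicates. They were 147 to 4653 bp wide (median 310), and the motif comparison took no account of width. A motif share can therefore differ because called regions are wider or narrower than the others. Single values were compared between sets of batches with two-sided permutation tests.

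The fit was checked on simulated counts. On regions drawn from the macrophage means, 200 of them changed by 1.5 on the log2 scale, it recovered 142 with the 7 Tyk2-ko libraries and 39 with the 3 Stat6-ko libraries, with 5 and 0 false calls. With nothing changed it called 0 regions for Stat1a-only and 0 for Stat3-ko.

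Alternatives were: no replicate block, size factors of the DESeq2 type (RLE), an offset against trends with GC content and mean level, no filter, the own research group alone, DESeq2, low-depth libraries left out, libraries with contradicting titles left out, regions near the mutated gene left out, each time alone, each research group left out, and each mutant replicate left out. In 8 libraries the title named another treatment than the treatment label, which was followed. The dendritic cell library of Tyk2-inact and the cultured libraries of Stat4-ko and Stat6-ko entered no comparison, since each stood alone or nearly so. Figures were drawn with matplotlib 3.10.9.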

Results

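Chromatin accessibility was measured over 277237 regions in 496 libraries of sorted mouse spleen cells. The 5 cell types were macrophages, CD8 T cells, B cells, NK cells and dendritic cells. The mice were wild type or carried 1 of 12 mutations in the pathway that takes cytokine signals from Janus kinases to STAT transcription factors. Knockouts (ko) concerned Irf9, Stat1, Stat2, Stat3, Stat4, Stat5, Stat6 and Tyk2. The other lines made only the alpha or only the beta form of STAT1 (Stat1a-only, Stat1b-only), a hyperactive STAT5B (Stat5-hyp) or a TYK2 kinase without catalytic activity (Tyk2-inact).

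Homeostatic libraries, made without culture, numbered 80 for macrophages (35 wild type), 77 for CD8 T cells (33 wild type), 24 for B cells (12 wild type), 23 for NK cells (10 wild type) and 9 for dendritic cells (4 wild type). Total counts were 711322 to 13166578 per macrophage library, 973129 to 13409297 per CD8 T cell library, 2070898 to 6184373 per B cell library, 1313529 to 11939573 per NK cell library and 652021 to 4388258 per dendritic cell library. Cultured macrophages gave 49 untreated libraries (17 wild type, totals of 870476 to 3283034), 42 with IFN-beta for 1.5 h (16 wild type, 459467 to 4064324) and 46 with IFN-beta for 20 h (18 wild type, 779463 to 4242898). Cultured CD8 T cells gave 50 untreated libraries (21 wild type, 485902 to 7480447), 42 with 1.5 h of IFN-beta (17 wild type, 415419 to 5624819) and 54 with 20 h (23 wild type, 906923 to 9433892). In 15 libraries the total was far below the median of their cell type. Of the regions, 29573 lay at promoters, 136471 in introns, 13329 in other exons or untranslated regions, and 97864 between genes.

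The targeted genes were read first, in CPM over the regions inside each gene that lost their signal. These regions were chosen by a low signal in homeostatic libraries of the same line. A small remainder there follows from this choice and does not check the genotype. They numbered 2 of 13 in Stat2-ko, 4 of 31 in Stat1-ko, 1 of 21 in Stat3-ko, 1 of 3 in Irf9-ko and 1 of 24 in Tyk2-ko. Stat2-ko kept 1.63% of the wild type signal in homeostatic macrophages (3 libraries against 5) and 0.969% in CD8 T cells (3 against 5). In Stat5-ko, which removes the neighbours Stat5a and Stat5b on chromosome 11, 36 of 38 regions were lost. The remaining signal was 1.20% in macrophages (3 against 8), 10.3% in B cells (4 against 8) and 12.4% in CD8 T cells (4 against 8). In cultured CD8 T cells it was 50.9% untreated and 47.9% after 20 h of IFN-beta, where 1 of the 4 libraries labelled Stat5-ko reached the wild type level at each time. Stat1-ko kept 4.24% in macrophages and 9.66% in CD8 T cells (2 libraries each). Stat3-ko had 0 reads over 1 region of Stat3 in every library except 1 of NK cells, where the wild type mean was 0.880 CPM in macrophages and 1.18 CPM in CD8 T cells. Irf9-ko kept 33.1% in macrophages and 37.4% in CD8 T cells because 1 of the 3 libraries labelled Irf9-ko in each stood at 99.1% and 112% of the wild type mean. That batch held no wild type, so that these libraries added nothing to the comparisons. Tyk2-ko had 0 reads over the Tyk2 region on chromosome 9 in homeostatic macrophages (7 libraries, wild type mean 0.224 CPM). The signal that could show the loss of Stat4 was weak, at 48.4% of wild type in macrophages. No region marked the lesions of Stat1a-only, Stat1b-only, Stat5-hyp or Stat6-ko. In Tyk2-inact, which makes the protein, 2 of 23 regions over Tyk2 also lost their signal by the same rule.

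The first question was which chromatin of resting spleen cells depends on the interferon branch, made of TYK2, STAT1, STAT2 and IRF9. The promoter region of Ifi27l2a, an interferon-induced gene of the mitochondrial membrane family (12:103443171-103444154), fell in macrophages by 2.57 ± 0.29 (SE) on the log2 scale in Irf9-ko (3 against 5 libraries, 2 pairs in a shared batch), by 2.31 ± 0.42 in Stat1-ko (2 against 8, 2 pairs), by 2.81 ± 0.30 in Stat2-ko (3 against 5, 3 pairs), by 1.96 ± 0.16 in Tyk2-inact and by 1.92 ± 0.17 in Tyk2-ko (7 against 7 each). In CD8 T cells it fell by 3.13 ± 0.47, 2.34 ± 0.44, 3.19 ± 0.45, 2.25 ± 0.24 and 1.92 ± 0.18 in the same order. The largest of the 10 adjusted p-values was 0.0468. In Stat1a-only and Stat1b-only the region stayed between −0.01 and 0.04 in both cell types, with SE of 0.21 to 0.28. It was also called lower in Stat5-ko CD8 T cells (−1.04 ± 0.27) and B cells (−0.55 ± 0.17), and was not called in NK cells of Tyk2-inact (−0.69 ± 0.49) or Tyk2-ko (−1.17 ± 0.50). A region 5.76 kb from the start of Trim30d, a member of an interferon-induced ubiquitin ligase family (7:104501662-104502475), moved the other way and rose in macrophages of all 5 mutants, from 1.80 ± 0.32 in Stat2-ko to 2.58 ± 0.20 in Tyk2-ko. In CD8 T cells it was not called in any mutant, with values from −0.76 to 0.73, and in B cells it was called lower in Stat5-hyp (−1.45 ± 0.21).

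In macrophages regions of several antiviral genes closed. The promoter region of Oas1a, a sensor of viral double-stranded RNA (5:120907443-120907815), fell by 4.59 ± 0.90 in Irf9-ko, 3.69 ± 0.33 in Tyk2-inact and 4.05 ± 0.39 in Tyk2-ko. A region in an intron of Ifi27 (12:103437651-103438058) fell by 2.97 ± 0.47 in Irf9-ko and 2.53 ± 0.38 in Tyk2-ko. The promoter region of Ifi44 (3:151749503-151750175) fell by 3.39 ± 0.37 in Tyk2-inact, and the Irf9 promoter region (14:55604840-55605197) fell by 1.97 ± 0.20 in Tyk2-inact and 2.21 ± 0.22 in Tyk2-ko. Called regions numbered 25 in Irf9-ko (15 higher, 10 lower), 11 in Stat1-ko (8 higher, 3 lower), 446 in Stat2-ko (66 higher, 380 lower), 483 in Tyk2-inact (136 higher, 347 lower) and 391 in Tyk2-ko (140 higher, 251 lower), of 171075 tested. The balance in Tyk2-ko depended on scaling, with 220 higher and 231 lower by RLE size factors and 191 and 198 with a GC and abundance offset. DESeq2 within the own research group called 1, 1, 5, 103 and 115 in the same order, and edgeR without the replicate block 11, 7, 42, 121 and 65. Without replicate 3 the count was 1 in Irf9-ko and 12 in Stat2-ko (727 without replicate 1), and in Stat1-ko it was 0 without replicate 1 and 6 without replicate 2. Among 230 regions near interferon-stimulated genes, 8 fell and 3 rose in Irf9-ko (18 lower adjusted over the list alone), 8 fell in Stat2-ko (14), 33 in Tyk2-inact (67) and 23 in Tyk2-ko (57). The list was lower by camera in all 5 mutants. It held with an estimated correlation in Irf9-ko (adjusted p = 0.0321), Tyk2-inact (2.10e-05) and Tyk2-ko (0.000242), while adjusted p = 0.571 with an estimated correlation in Stat1-ko and 0.254 in Stat2-ko. Motifs of the factor complex STAT1-STAT2-IRF9 (ISRE) lay in 27.1% of the regions lower in Tyk2-inact against 8.48% of the others, in 26.7% for Tyk2-ko and in 18.9% for Stat2-ko. Markers of B cells were lower in macrophage libraries of Stat2-ko (median −0.74), Tyk2-inact (−0.41) and Tyk2-ko (−0.40), and those of T cells higher in Irf9-ko (0.78), by camera with the preset correlation only.

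In CD8 T cells Tyk2-ko (6 against 6 libraries) lowered regions at Mx1, an inhibitor of virus replication (16:97460622-97460851, −3.38 ± 0.43), at Iigp1, a GTPase against intracellular parasites (18:60375492-60376131, −2.63 ± 0.36), and at Usp18, a brake on the interferon receptor (6:121247887-121248181, −1.85 ± 0.23). The region at Usp18 fell by 2.23 ± 0.31 in Tyk2-inact (4 against 6). Called regions of 154202 tested numbered 1 in Irf9-ko (Ifi27l2a), 3 in Stat1-ko, 23 in Stat2-ko (17 higher, 6 lower), 49 in Tyk2-ko (11 higher, 38 lower) and 2268 in Tyk2-inact (2169 higher, 99 lower). The count for Tyk2-inact was 85, 1213, 5355 and 89 without replicates 1, 2, 3 and 4, 33 without the replicate block, 6396 with RLE size factors and 9 by DESeq2 (16 in Tyk2-ko, 4 in Stat2-ko). That of Stat2-ko was 12 without replicate 1 and 9 without replicate 3, and its balance became 13 higher and 11 lower with RLE size factors and 22 and 18 with a GC and abundance offset. In Stat1-ko the count was 0 without replicate 1, and in Irf9-ko 0 without replicate 2 or 3. The interferon-stimulated list was lower in Tyk2-ko with 15 of 222 regions called (38 adjusted over the list alone, adjusted p = 0.0321 with an estimated correlation). It was lower in Tyk2-inact with 23 regions (41) only with the preset correlation (adjusted p = 0.254 with an estimated correlation). ISRE motifs lay in 44.7% of the regions lower in Tyk2-ko and 33.3% of those lower in Tyk2-inact, against 8.93% and 8.92% elsewhere. The regions higher in Tyk2-inact carried PU.1 motifs in 15.9% against 10.6%, and T cell markers were lower in these libraries by camera (median −0.32, adjusted p = 0.989 with an estimated correlation).

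NK cells (3 mutant and 3 wild type libraries per line) lost the Ifi44 promoter region by 3.03 ± 0.39 in Tyk2-inact (adjusted p = 0.000249) and by 2.88 ± 0.37 in Tyk2-ko (0.000181). Called regions numbered 19 and 13 of 124663, against 2 and 0 without replicate 2, 6 and 5 without replicate 3, and 7 and 8 by DESeq2. The interferon-stimulated list had 1 lower region in each, with 19 and 15 of 186 adjusted over the list alone (adjusted p = 0.410 with an estimated correlation for both). In dendritic cells of Tyk2-ko (4 against 4) edgeR called 0 of 132193 regions, with 3409 at an unadjusted p under 0.05 and 0 by DESeq2. There the Ifi27l2a promoter region measured −1.16 ± 0.31 (adjusted p = 1). Of the 4 mutant libraries 2 shared a batch, and the sample name of 1 reads TYK2KO where those of the others read TYK2CMV.

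**Figure D1:**
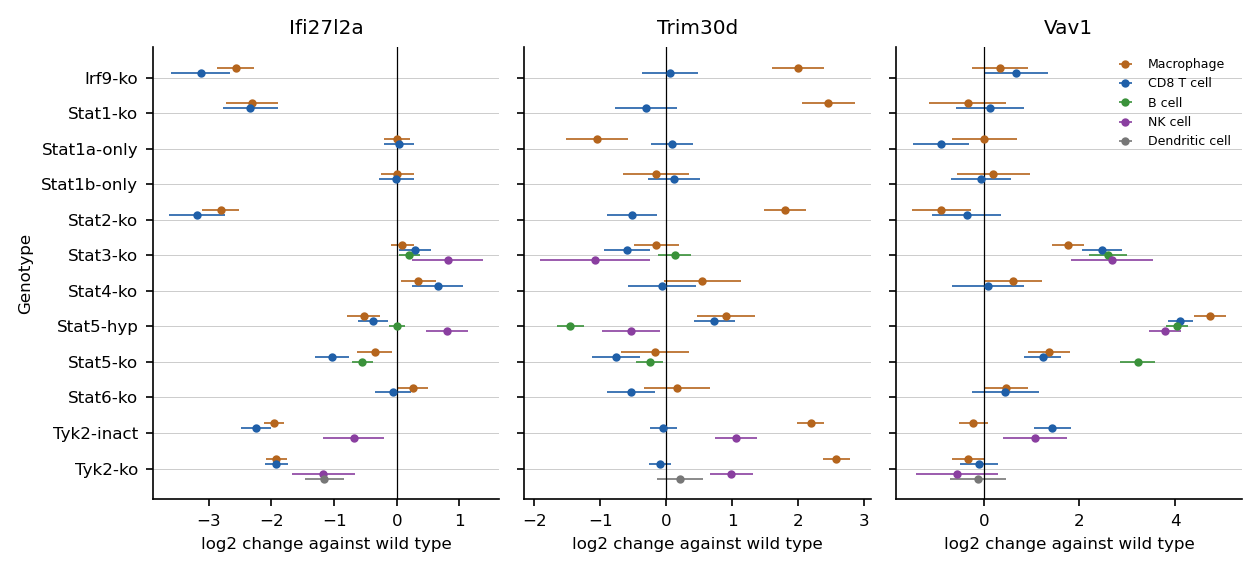
Log2 accessibility change against wild type of the own research group for the promoter region of Ifi27l2a, a region by Trim30d and an intron region of Vav1, by genotype (vertical axis) and cell type (colour), homeostatic libraries. Points are edgeR estimates and bars 1 SE. Ifi27l2a lies between −1.92 and −3.19 in both cell types with all 5 interferon-branch mutants.

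The 105 regions that rose by more than 1 with IFN-beta in cultured wild type CD8 T cells were also read in homeostatic cells without added interferon. Camera called the set in 15 of 36 comparisons. It was lower in macrophages of Stat1-ko (median −0.55 over 103 regions), Tyk2-inact (−0.32, 12 regions lower) and Tyk2-ko (−0.34, 9 lower) and in CD8 T cells of Tyk2-ko (−0.20, 7 lower), and these 4 held with an estimated correlation. In Stat5-hyp CD8 T cells 24 of the regions rose and 0 fell (29 and 6 adjusted over the set alone, median 0.26, adjusted p = 0.0861 with an estimated correlation).

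Several regions called in these mutants lay on the chromosome of the mutated gene. The windows of 10 Mb used here include the mutated gene itself, so that regions lost with it can be among the calls. Within 10 Mb of it were 4 of the 11 called regions of Stat1-ko macrophages, 11 of 446 of Stat2-ko, 13 of 483 of Tyk2-inact and 14 of 391 of Tyk2-ko, where the share of tested regions gave odds ratios of 83.6, 3.98, 4.51 and 6.06. In Stat2-ko the largest gains away from the gene lay together on chromosome 11, with St6galnac1, a sialyltransferase (11:116752099-116752449, 4.77 ± 0.58 in macrophages), Mxra7 and Prcd, and in CD8 T cells with another region at St6galnac1 (5.04 ± 0.59) and Tnrc6c (3.42 ± 0.51). A region by 5830416I19Rik (5:64038307-64038845) rose by 3.30 ± 0.49 in Stat2-ko macrophages and fell by 2.36 ± 0.34 in those of Stat6-ko. Exon regions of Stat1 itself rose in Irf9-ko macrophages (1:52123026-52123335, 3.13 ± 0.44) and in Stat2-ko CD8 T cells (1:52126430-52126706, 1.84 ± 0.35), but measured 0.00 and 0.50 without 1 replicate (replicate 3 and replicate 1). In 4 of the 496 libraries, from group TD in each case, reads over the exons of Stat1 exceeded 10 times the usual level.

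The paired alleles asked whether losing the kinase differs from losing its activity. Against Tyk2-ko, Tyk2-inact macrophages (7 libraries each) were higher at Mid1, a ubiquitin ligase gene at the border of the pseudoautosomal region (X:169993670-169994869, 5.10 ± 0.49), and lower at Cdon, a cell surface receptor gene on chromosome 9 (9:35483411-35484913, −2.12 ± 0.24). Of 37 called regions (27 higher, 10 lower) 26 lay on chromosome 9, which carries Tyk2, between 32.8 and 48.5 Mb. Tyk2 itself lies near 9:21120236, and 0 of the 37 lay within 10 Mb of it. No region of the interferon-responsive set was called between the alleles in macrophages. In CD8 T cells (4 against 6 libraries) 6892 regions differed, 6540 of them higher in Tyk2-inact, including regions at Mid1 (5.30 ± 0.58), Ccl7, a monocyte attractant (2.58), H2-Eb1 (1.56) and Csf1r, the macrophage growth factor receptor (1.49). The count was 369, 4123, 13117 and 371 without Tyk2-inact replicates 1, 2, 3 and 4, 29 without the replicate block and 1 by DESeq2, so that the size of this difference is not fixed by these data. Markers of dendritic cells were higher there with 3 of 9 regions called (adjusted p = 0.989 with an estimated correlation). Stat1a-only differed from Stat1b-only in 0 regions in macrophages (4 against 3, 10322 at an unadjusted p under 0.05 and 0 by DESeq2) and in 0 in CD8 T cells (4 against 3, 3905 and 0). Within their research group alone edgeR called 166 in macrophages (21 higher, 145 lower).

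Each STAT1 form alone gave at most 1 call against wild type in homeostatic cells. In macrophages 1 region, in an intron of Focad, a tumour suppressor gene (4:88409282-88409687), fell by 1.77 ± 0.32 in Stat1a-only (0 calls without any 1 of its 4 replicates and by DESeq2, 25 within the own research group), and Stat1b-only gave 0 calls (5653 at an unadjusted p under 0.05, 0 by DESeq2). In CD8 T cells edgeR called 0 regions for both forms, with 4016 and 4156 at an unadjusted p under 0.05 and 0 and 0 by DESeq2.

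The lines of STAT5, which relays interleukin-2, interleukin-7 and growth factor signals, had the most regions called against wild type by edgeR. This held within each cell type in which they were measured. The lines differed in numbers of libraries, and no test ranked them. CD8 T cells with hyperactive STAT5B (5 against 8 libraries) gained accessibility at its known targets Il2rb, the interleukin-2 receptor beta chain (15:78501999 start, 2.37 ± 0.22), Pim1 (1.83 ± 0.19) and the feedback inhibitor Socs2 (1.66 ± 0.24). Effector genes rose with Ifng, the macrophage-activating cytokine (2.62 ± 0.27), Cx3cr1 (2.55 ± 0.36), Ccl5 (1.94 ± 0.21) and Ccl4 (2.09 ± 0.25). Regions by the T cell receptor segments Traj61 (14:54152771-54153264, −3.37 ± 0.48) and Trdv2-1 (−5.54 ± 1.06) fell. In all 7920 of 154202 regions were called, 5832 higher and 2088 lower (4995 without replicate 1, 3305 without replicate 4, 3520 by DESeq2). Of 109 regions near effector CD8 T cell genes 35 rose and 1 fell (52 and 2 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0116). Of 82 regions near cytokine feedback genes and STAT5 targets 21 rose and 0 fell (adjusted p = 0.476 with an estimated correlation), and of 63 near guanylate-binding and immunity-related GTPases 6 rose and 1 fell (0.894). Markers of NK cells rose beside them with 3 of 9 regions called (median 0.72, adjusted p = 0.989 with an estimated correlation). GAS motifs, bound by STAT dimers, lay in 31.9% of the higher regions against 15.8% of the others, without account of region width.

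Stat5-ko CD8 T cells (4 against 8 libraries) lost a region at Il7r, the interleukin-7 receptor that keeps naive cells alive (−2.11 ± 0.37), at Ccnd2, a cyclin (−1.65 ± 0.35), and by the T cell receptor segment Trav13-4-dv7 (14:53757820-53758079, −3.91 ± 0.93). They gained regions at Gzmk, a granule protease (2.86 ± 0.27), Klrg1 (2.54 ± 0.36) and Ifng (1.94 ± 0.31), at the inhibitory receptors Ctla4 (2.14 ± 0.32), Pdcd1 (1.95 ± 0.33) and Havcr2 (1.29), and at Il10 (2.55 ± 0.30). Called regions numbered 7968, 2889 higher and 5079 lower (2767 without replicate 2, 1819 without replicate 3, 5049 by DESeq2). Replicate 4 held 66.9 CPM over the deleted part of the targeted genes where the others held 2.12 to 8.72, and without it 7119 regions were called, 3691 of them higher. The balance of gains and losses depended on scaling, since 36.3% of the called regions were higher with TMM, 52.6% with RLE size factors and 58.6% with a GC and abundance offset. Of 109 effector regions 21 rose and 2 fell (24 and 5 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation), of 103 near naive T cell genes 11 fell (20, adjusted p = 0.886), of 50 near inhibitory receptors 8 rose and 2 fell (camera adjusted p = 0.180), and of 59 near inflammatory cytokines and chemokines 8 rose (adjusted p = 0.571 with an estimated correlation). AP-1 motifs lay in 31.4% of the higher regions against 15.5%, and GAS motifs in 25.3% of the lower against 16.1%. T cell markers measured −0.41 and macrophage markers 0.53 at the median in these libraries, neither passing camera.

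Stat5-hyp macrophages (3 against 8 libraries) gained regions at Tnfrsf9, a costimulatory receptor (2.21 ± 0.43), and Il2rb (1.71 ± 0.41). They lost regions at Spic, the factor that makes red pulp macrophages (−1.38 ± 0.37), Csf1r (−1.11 ± 0.30), Hmox1, which breaks down haem (−1.18), Ciita, the master regulator of MHC class II (−1.53), and Fos (−1.34). Called regions numbered 2530, 551 higher and 1979 lower. This count rests on single libraries and on scaling: it was 16477, 6 and 316 without replicates 1, 2 and 3, 87 without the replicate block and 5 by DESeq2, and 71.2% of 1626 called regions were higher with RLE size factors against 21.8% with TMM. Red pulp macrophage genes had 4 lower of 83 regions (14 adjusted over the list alone, adjusted p = 0.886 with an estimated correlation), MHC class II genes 2 of 78 (0.912), immediate early and stress genes 2 of 129 (18 over the list alone, 0.912) and alternative activation genes 3 of 75. T cell markers were higher in these libraries with 3 of 14 regions called (median 0.90) and macrophage markers lower with 2 of 10 (−0.67, adjusted p = 0.989 with an estimated correlation for both). PU.1 motifs, of the factor that sets macrophage identity, lay in 26.9% of the lower regions against 10.7% of the others.

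Stat5-ko macrophages (3 against 8) gained regions at Irgm1, a GTPase against intracellular bacteria (3.44 ± 0.43), Slc40a1, the iron exporter (3.50 ± 0.57), Csf2rb (4.98 ± 0.68), Tgm2 (3.39 ± 0.42) and the proliferation gene Mki67 (2.89 ± 0.29). Called regions numbered 4226, 4020 higher and 206 lower (568 without replicate 1, 405 by DESeq2). MHC class I genes had 4 higher of 64 regions (9 adjusted over the list alone, adjusted p = 0.912 with an estimated correlation), and 19 of the 145 JAK-STAT component regions fell, among them those of Stat5a (−6.19 ± 0.62) and Stat5b (−5.72 ± 0.64). Erythroid markers were higher with 4 of 6 regions called (median 1.37, adjusted p = 0.520 with an estimated correlation). PU.1 motifs lay in 4.35% of the higher regions against 11.1% of the others.

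In B cells (4 against 8 libraries for each line) Stat5-hyp raised a region at Fat1, a large cadherin (8:44935682-44936142, 3.11 ± 0.30), and at Il2rb (1.41 ± 0.37), and lowered regions at Ctla4 (−1.35 ± 0.20), Pdcd1 (−1.04 ± 0.17) and Cxcl1 (−2.27 ± 0.39). Of 77594 regions 3714 were called, 1213 higher and 2501 lower (2240, 2474 and 2203 without replicates 1, 2 and 4, 473 by DESeq2), and 5 of 34 regions of inhibitory receptors fell (adjusted p = 0.410 with an estimated correlation). Stat5-ko B cells had 3926 called regions, 2710 higher and 1216 lower (2133, 2259 and 2508 without replicates 1, 2 and 3, 803 by DESeq2). Replicate 4 held 49.2 CPM over the deleted part of the targeted genes where the others held 0.676 to 4.44, and more regions were called without it. Il10 rose (1.19), as did Tbx21, a T-box factor (0.76), while Il7r (−1.14), Lef1 (−1.17 ± 0.22) and the antiviral genes Oas2 (−0.87) and Rtp4 (−0.84) fell. In NK cells Stat5-hyp (4 against 5) raised regions at Zfpm1, a partner of GATA factors (8:122297884-122298225, 3.87 ± 0.41), Osm, a cytokine gene (1.76 ± 0.22), Cx3cr1 (1.80 ± 0.22), Havcr2 (1.71 ± 0.28) and Il4ra (2.02 ± 0.26). Of 124663 regions 1849 were called, 1451 higher and 398 lower (159 without replicate 2, 270 without replicate 4, 453 by DESeq2). Cytokine feedback genes had 7 higher of 79 regions (12 adjusted over the list alone, adjusted p = 0.886 with an estimated correlation). GAS motifs lay in 33.1% of the regions higher in Stat5-hyp B cells against 21.1% of the others, and in 32.1% in NK cells (odds ratio 2.15 over the others).

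A region in an intron of Vav1, a signalling adaptor of blood cells (17:57291910-57292224), rose in all Stat5-hyp cells measured, by 4.73 ± 0.34 in macrophages, 4.11 ± 0.26 in CD8 T cells, 4.05 ± 0.23 in B cells and 3.79 ± 0.34 in NK cells. It rose also in Stat5-ko B cells (3.22 ± 0.37) and CD8 T cells (1.23 ± 0.38), and in Stat3-ko macrophages (1.76 ± 0.34), CD8 T cells (2.47 ± 0.41) and B cells (2.60 ± 0.39). The region was also called in Tyk2-inact CD8 T cells (1.43 ± 0.39, adjusted p = 0.0373). The sample names of the libraries of Stat3-ko and Stat5-ko mention Vav, those of Stat5-hyp and Tyk2-inact do not. In these data reads from an inserted copy of Vav1 sequence cannot be told from reads of the locus.

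In homeostatic cells of Stat3-ko, Stat4-ko and Stat6-ko few regions were called. Stat3-ko (4 against 4 libraries, in NK cells 3 against 2) had 6 called regions in macrophages, 4 in CD8 T cells, 7 in B cells and 1 in NK cells, all of them higher (2, 3, 3 and 0 by DESeq2). Without single replicates the counts were 1 to 4, 0 to 3, 3 to 22 and 0 to 3, with 0 in CD8 T cells without replicate 2 and 22 in B cells without replicate 2. Within the own research group alone edgeR called more regions in macrophages and CD8 T cells, and 2014 in NK cells, against 2 wild types. The calls counted first, in macrophages, CD8 T cells and B cells, included the promoter region of Arhgef4, an exchange factor for Rho GTPases (1:34677951-34678649, 1.42 ± 0.28 in both macrophages and B cells), Gm4951, an interferon-induced GTPase gene, in CD8 T cells (18:60211425-60212168, 2.13 ± 0.33) and Tgfbr1, the receptor of transforming growth factor beta, in B cells (4:47351419-47353986, 0.81 ± 0.12). Stat4-ko had 0 calls in macrophages (3 against 8, 5159 at an unadjusted p under 0.05, 0 by DESeq2) and in CD8 T cells (3 against 7, 6176 and 0). Stat6-ko (3 against 3) had 6 calls in macrophages, 3 of them within 10 Mb of Stat6, and 20 in CD8 T cells (1 and 3 by DESeq2, 2289 and 318 without the replicate block, 5592 and 14789 at an unadjusted p under 0.05). Replicates 2 and 3 of Stat6-ko macrophages had closer counts than independent counting gives (chi-square per degree of freedom 0.809), so that this arm holds perhaps only 2 independent libraries. Libraries of unlike genotype were also close, down to 0.933 for Tyk2-ko and Tyk2-inact CD8 T cells of 1 batch. The value alone therefore does not settle this. Without replicate 1, 2 or 3 the calls were 0, 1 and 8 in macrophages, and without replicate 2 or 3 they were 6 and 13 in CD8 T cells. There a region 25.3 kb from the start of Col19a1 rose (1:24612620-24612887, 3.93 ± 0.44), which lies in a stretch resembling mitochondrial DNA, and a region 47.5 kb from the start of Pgm2, a sugar phosphate mutase gene, fell (−1.57 ± 0.27).

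**Figure D2:**
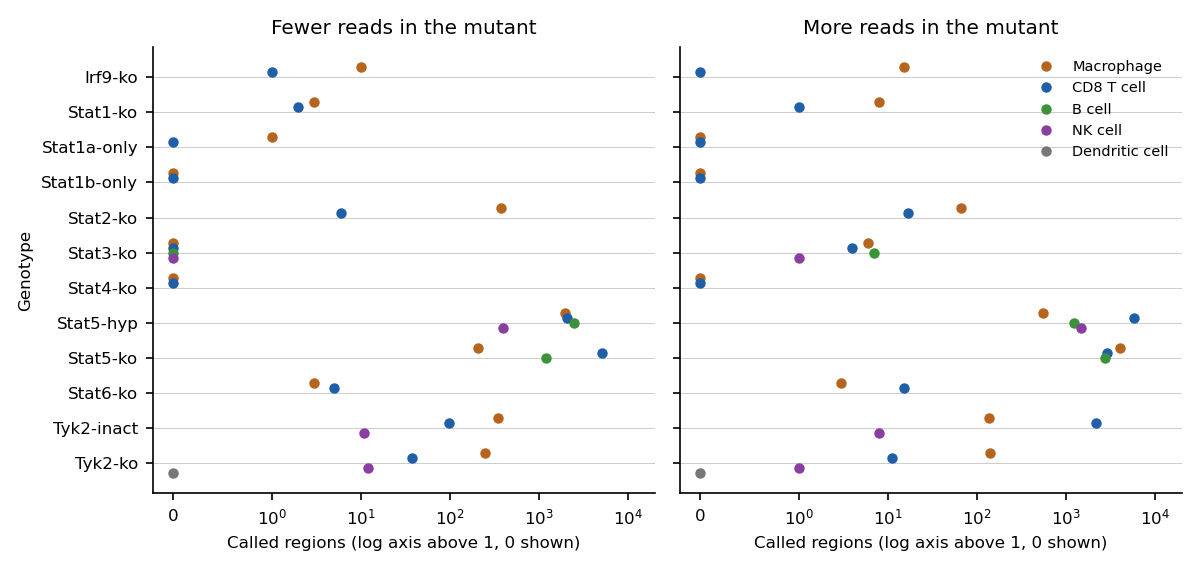
Number of regions called lower (left panel) and higher (right panel) than wild type by edgeR, on a log axis above 1, per genotype (vertical axis) and cell type (colour) in homeostatic libraries. Stat5-hyp reaches 5832 higher regions and Stat5-ko 5079 lower regions, both in CD8 T cells.

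Over the 540 tests of fixed gene lists in homeostatic comparisons camera made 140 calls, and 5 held with an estimated correlation: the interferon-stimulated genes in 4 comparisons and the effector genes in Stat5-hyp CD8 T cells. Cell cycle genes had 7 regions higher and 5 lower over all 36 comparisons (12 and 16 adjusted over the list alone), and cholesterol and lipid genes 3 and 5 (5 and 6). Marker lists gave 22 calls in 360 tests, 0 of them with an estimated correlation. In Tyk2-inact CD8 T cells the median and mean of several lists differed in sign.

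Culture itself changed most regions. Wild type macrophages cultured for 20 h (17 libraries against 35) closed a region 2.89 kb from the start of Jun, an immediate early factor (4:95049172-95049501, −2.64 ± 0.24), the Jun promoter region itself (−1.09 ± 0.09), and regions at Fos (−1.45 ± 0.12), Egr1 (−1.20 ± 0.10), H2-Ab1, an MHC class II chain (−1.12 ± 0.12), Spi1, which encodes PU.1 (−1.09), and Csf1r (−0.96). They opened regions at Rnf182 (13:43662384-43663339, 2.59 ± 0.22), Itga11, a collagen receptor (2.50 ± 0.24), and the chemokine gene Cxcl10 (1.67 ± 0.16). Of 76204 regions 26458 rose and 25831 fell. Of 112 regions near immediate early and stress genes 92 fell and 5 rose (adjusted p = 0.130 with an estimated correlation), of 62 near MHC class II genes 41 fell (0.301), of 129 near interferon-stimulated genes 68 fell and 27 rose (0.273), of 41 near cell cycle genes 25 fell (0.281) and of 39 near cholesterol and lipid genes 22 fell (0.389). T cell markers rose with 8 of 8 regions called (median 1.33, adjusted p = 0.848 with an estimated correlation), while macrophage markers measured −0.54. B cell markers had 6 of 11 regions higher (median 0.57) and NK cell markers 4 of 5 (1.02), neither list passing camera. Cultured and homeostatic cells were never made in the same batch.

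CD8 T cells in culture (21 against 33 libraries) also closed a region 3.67 kb from the start of Jun (4:95047980-95049122, −1.78 ± 0.20). They opened regions of naive T cell genes, with Klf2, which keeps T cells circulating (0.76 ± 0.08), Ccr7, the receptor for homing to lymph nodes (0.70), and Tcf7 (0.66), and of MHC class I genes with H2-D1 (0.88 ± 0.09) and H2-K1 (0.80). Regions at Zeb2 (−0.93), Cd44 (−0.70) and the RNA sensor gene Ifih1 (−0.96 ± 0.10) closed. Of 64570 regions 19510 rose and 15614 fell. Of 79 naive T cell regions 49 rose and 0 fell (adjusted p = 0.453 with an estimated correlation), of 36 MHC class I regions 22 rose and 2 fell (0.301) and of 84 JAK-STAT component regions 45 rose and 6 fell (0.323). T cell markers had 8 of 14 regions higher, NK cell markers 5 of 8 lower and erythroid markers 3 of 3 lower, none of these lists passing camera.

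Whether mutant cells taken straight from the spleen lean towards the cultured state was asked pair by pair, with the culture change taken from the other research groups so that no library was shared. Across regions, which are not independent replicates, every pair correlated positively with the culture change in 4 of 24 lines, where signs drawn at random give 2.84: Irf9-ko (mean r = 0.202, 2 pairs) and Stat3-ko macrophages (0.179, 4 pairs), and Stat3-ko (0.0662, 4 pairs) and Stat5-ko CD8 T cells (0.295, 4 pairs). The highest mean was that of Stat5-hyp macrophages (0.410), positive in 2 of 3 pairs. Every pair correlated negatively in Stat1-ko (−0.422, 2 pairs) and Stat4-ko macrophages (−0.207, 3 pairs). Where 6 or more pairs allowed an exact sign-flip permutation test, its p was 0.875 for Tyk2-inact macrophages, 0.953 for Tyk2-ko macrophages and 0.438 for Tyk2-ko CD8 T cells.

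IFN-beta was added to ask how fast chromatin opens and which members the response needs. In wild type CD8 T cells 1.5 h of IFN-beta (17 libraries against 21 untreated) opened a region in an intron of Stat1 (1:52169159-52169784, 1.79 ± 0.19), Slfn1, a brake on T cell growth (11:83122370-83122802, 1.55 ± 0.25), Igtp, an immunity-related GTPase (11:58193296-58193967, 1.36 ± 0.19), Socs1, a feedback inhibitor (0.82 ± 0.09), and Il4ra (0.73 ± 0.09). After 20 h (23 against 21) the largest gains lay at Stat1 (1:52163659-52164450, 2.56 ± 0.17), Slfn1 (2.04 ± 0.19), Usp18 (6:121271347-121271758, 1.89 ± 0.18), Zbp1, a sensor of nucleic acids (2:173205891-173206319, 1.81 ± 0.19), Irf7 (7:141261190-141261584, 1.72 ± 0.19), Ifit3 (19:34576974-34578525, 1.70 ± 0.16) and Mx1 (16:97445097-97447564, 1.69 ± 0.16). Losses were smaller, the largest with a named gene at St8sia6 with −0.81 ± 0.18 at 1.5 h and −0.87 ± 0.15 at 20 h. Called regions of 59352 were 1549 higher and 331 lower at 1.5 h, and 3123 higher and 1461 lower at 20 h. Without group MM 47 and 985 were called, without a low-count filter 527 and 3010, without libraries whose title names another treatment 2531 and 1258, and by DESeq2 2913 and 1668.

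Interferon-stimulated genes had 51 of 134 regions higher at 1.5 h (79 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation) and 90 higher and 2 lower at 20 h (100 and 4, adjusted p = 0.000843). Guanylate-binding and immunity-related GTPases had 23 of 41 higher at either time, and MHC class I genes, with Psmb8 of the immunoproteasome (0.54 ± 0.06) and Tapbp (0.59), 10 of 39 at 1.5 h and 25 at 20 h. Cytokine feedback genes had 15 of 63 higher at 1.5 h and 25 at 20 h. With an estimated correlation the GTPases and the feedback genes held at both times, immediate early genes at 1.5 h and interferon-stimulated and MHC class I genes at 20 h. ISRE motifs lay in 30.0% of the regions higher at 1.5 h and 24.6% at 20 h, against 12.0% and 11.7% of the others, and GAS motifs in 45.1% at 1.5 h against 22.1%.

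Wild type macrophages gave 0 calls at 1.5 h (16 against 17 libraries, 2296 of 50293 at an unadjusted p under 0.05, 0 by DESeq2) and 0 at 20 h (18 against 17, 2063 and 0). The guanylate-binding and immunity-related GTPases were still higher as a list at 1.5 h (median 0.17 over 24 regions, adjusted p = 0.00308 with an estimated correlation) and interferon-stimulated genes at 20 h (0.17 over 80 regions, 6 higher adjusted over the list alone, adjusted p = 0.00826). Over the interferon-responsive regions, chosen in these CD8 T cells (100 of 105 tested there and 54 in macrophages), the mean 20 h response per batch was 0.63 (SD 0.69, 20 batches) in CD8 T cells and 0.06 (SD 0.08, 14 batches) in macrophages, a difference that this choice favours. As a set (47 regions in this test) they were higher in macrophages at both times (median 0.09 and 0.07, adjusted p = 0.00446 and 0.0253 with an estimated correlation).

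The CD8 T cell response differed by research group. The mean 20 h response of wild types was 1.91 (SD 0.11, 3 batches) in group MM, 1.36 (SD 0.02, 2 batches) in BS, 0.57 (SD 0.28, 4 batches) in VS, 0.37 (SD 0.24, 4 batches) in RM, 0.05 in the single batch of SK and 0.04 (SD 0.08, 6 batches) in TD. Group TD lay 0.84 below the others (two-sided exact permutation p = 0.00818 over 38760 splits of batches). Batches of the same group lay close together and are not independent, so that this p does not measure the spread between groups. On the list of interferon-stimulated genes fixed beforehand the 20 h means were 0.75 in MM, 0.59 in BS, 0.41 in VS, 0.34 in RM, 0.18 in SK and 0.06 in TD. Each group fitted alone, a step added after the data were seen, gave 5717 called regions at 20 h in MM (3339 higher), 878 in BS (519 higher), 173 in VS (168 higher), 57 in RM (39 higher) and 0 in TD (4011 at an unadjusted p under 0.05). At 1.5 h RM had 155, of which 149 were lower, MM 1666 (1394 higher) and VS 22 (21 higher).

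**Figure D3:**
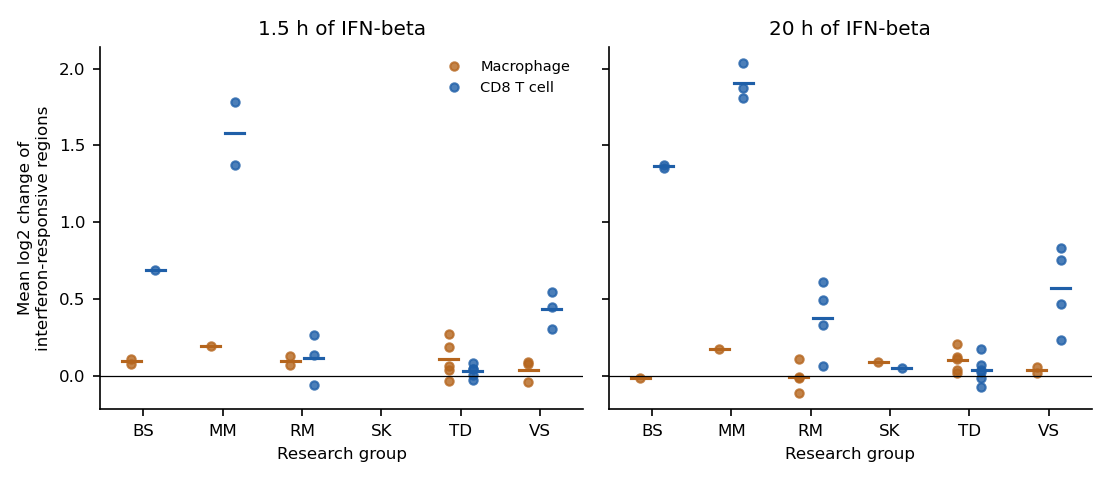
Mean log2 response to IFN-beta over the interferon-responsive regions (100 in CD8 T cells, 54 in macrophages) in wild type cells, 1 point per batch, by research group, for CD8 T cells and macrophages at 1.5 h and 20 h; bars mark means. At 20 h CD8 T cells of group MM stand at 1.91 and those of group TD at 0.04.

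Against all wild types pooled, the IFN-beta response of Irf9-ko CD8 T cells (8 treated and 4 untreated libraries) was lower at Stat1 (1:52169159-52169784, −2.33 ± 0.45, adjusted p = 0.0218), at Ifit3 (19:34576974-34578525, −2.02 ± 0.40, 0.0283) and at the promoter of Gm12185 (−1.54 ± 0.29, 0.0218), the only 3 called of 60976 regions. None was called without any 1 of its 4 replicates, without the replicate block or by DESeq2. Replicate 2 at 20 h held 2.38 CPM over the lost region of Irf9, where the other 20 h libraries held 0. Interferon-stimulated genes responded less by camera (median −0.36, 38 regions lower adjusted over the list alone, adjusted p = 0.236 with an estimated correlation). Irf9-ko came from group TD, whose own wild types did not respond, and against these alone the set of interferon-responsive regions differed by 0.01 in Irf9-ko and 0.03 in Stat2-ko. Against the pooled wild types it differed by −0.90 in Irf9-ko and −0.80 in Stat2-ko (adjusted p = 0.0380 and 0.368 with an estimated correlation).

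Within the responding groups, Tyk2-inact and Tyk2-ko CD8 T cells of group MM opened the interferon-responsive regions less than their own wild types. At 20 h the mean response was 1.05 in Tyk2-inact and 0.77 in Tyk2-ko against 1.91 (3 batches, lower in 3 of 3 for each). In 1 batch Tyk2-ko measured −0.06 with its untreated level 0.91 above wild type, and without that batch the means were 1.19 against 1.92. The set was lower with fry adjusted p = 0.00872 and 0.0108 over both times. On the fixed list of interferon-stimulated genes no such difference was seen (median −0.02 in Tyk2-inact and 0.06 in Tyk2-ko, fry adjusted p = 0.957 for both), and the interferon-responsive regions were chosen with these wild types among others. Stat1-ko of group BS measured 0.20 against 1.38 in 1 batch at 20 h (fry adjusted p = 0.0323 over both times). At 1.5 h it measured 0.08 and 0.83 in 2 batches against 0.69 in the single wild type batch (fry adjusted p = 0.246). Stat1a-only measured 0.89 against 1.36 in 2 batches at 20 h and 1.14 against 0.69 in 1 batch at 1.5 h, opposite directions that camera called with the preset correlation only (adjusted p = 4.79e-05 and 0.000836, with an estimated correlation 0.437 and 0.539). Stat1b-only was lower over both times by camera (median −0.23, adjusted p = 0.00499, with an estimated correlation 0.614), though higher in the only batch with both, 0.87 against 0.69 at 1.5 h, and fry called neither form. Stat3-ko at 1.5 h opened the regions more than wild types of group VS by camera (median difference 0.59, adjusted p = 0.178 with an estimated correlation). Stat5-ko of group RM moved the same way at 1.5 h, with 0.95 against 0.14 in 1 batch. Its single library kept most of the wild type signal over the targeted genes. These own-group tests were added after the data were seen.

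Against pooled wild types, Stat1a-only CD8 T cells differed in 5289 regions of the response (2076 higher, 3213 lower, with RLE size factors 1144 and 4686), such as Casp8, which starts cell death (2.84 ± 0.75), and Ccr3, a chemokine receptor gene (−2.80 ± 0.52). Markers of T cells were lower (median −0.64) and of macrophages higher (0.62) in the untreated libraries of this line, and without replicate 3 or its batch 0 regions were called (13976 without replicate 1, 8570 without replicate 2). Stat1-ko had 1382 called regions at 20 h alone (323 higher, 1059 lower). Tyk2-inact had 1 called region, at Ifit3b (19:34607311-34608134, 1.94 ± 0.37). The other CD8 T cell lines had 0 calls, with 5015 regions at an unadjusted p under 0.05 in Stat1-ko, 1884 in Stat1b-only, 2842 in Stat2-ko, 2948 in Stat3-ko, 2457 in Stat5-ko and 5000 in Tyk2-ko. DESeq2 within the own research group gave 14 in Tyk2-ko (5 higher, 9 lower), 14 in Tyk2-inact (1 higher, 13 lower) and 0 in the other lines, Stat1a-only included, and edgeR within the own group gave 125 in Tyk2-ko, 57 in Tyk2-inact and 138 in Stat1a-only. All 9 macrophage lines had 0 calls, with 2025 to 2582 regions at an unadjusted p under 0.05 and 0 in each by DESeq2. Wild type macrophages had 0 calls themselves with IFN-beta, so that these counts could hardly show a lost response. Over 270 list tests of the response camera made 28 calls, 0 of them with an estimated correlation. In untreated cultured cells 33 of 270 list tests passed and 0 held with an estimated correlation, among them lower interferon-stimulated genes in Tyk2-ko CD8 T cells (median −0.48, 15 regions adjusted over the list alone, adjusted p = 0.796 with an estimated correlation) and higher effector genes in Stat5-ko CD8 T cells (0.50, 19 of 51 regions, 0.0505).

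**Figure D4:**
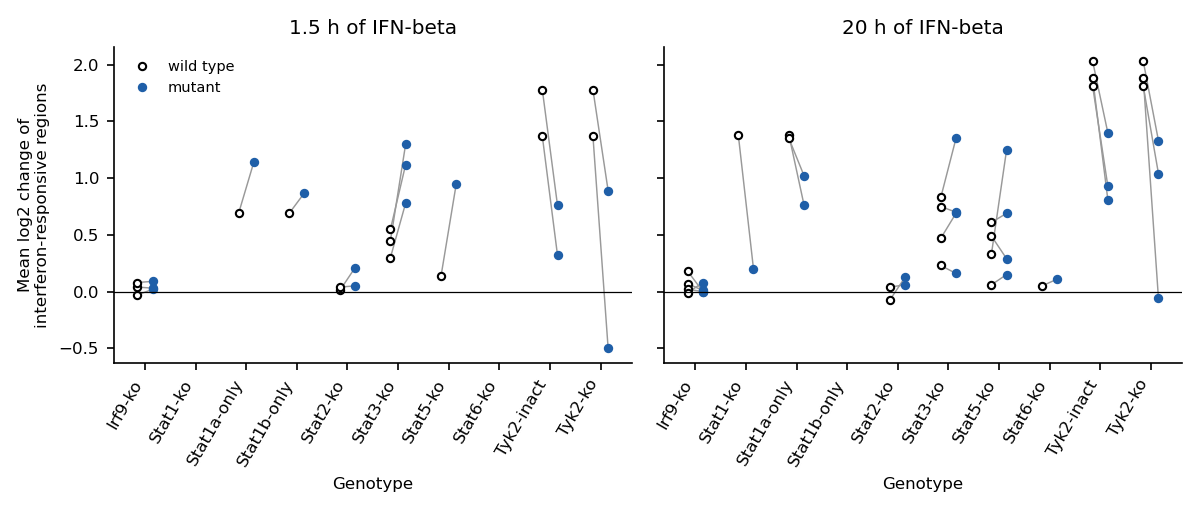
Mean log2 response to 1.5 h and 20 h of IFN-beta over the 100 tested interferon-responsive regions in CD8 T cells, with each mutant (filled) joined to the wild type of its batch (open), by genotype. At 20 h Tyk2-inact and Tyk2-ko lie below their wild types in 3 of 3 batches each.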

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

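The permutation tests between research groups and the tests on swapped labels, regions already open, depth, the regions that differed between both Tyk2 alleles and the exons of Stat1 were chosen after the result was seen.

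Over the interferon-responsive regions, wild type CD8 T cells of research group TD responded little to 20 h of IFN-beta. The mean response was 0.04 (SD 0.08, 6 batches). The batches of TD lay below the pooled batches of the other groups (two-sided exact permutation p = 0.00818 at 20 h and 0.0480 at 1.5 h). Batches of the same group are not independent, so that these p-values do not measure the spread between groups. Group TD was not set apart from each other group. The single batch of SK had 0.05 at 20 h, and at 1.5 h the mean was 0.11 (SD 0.17) in RM against 0.03 in TD. Swapped treated and untreated labels are argued against by the lowest batch, at −0.07, and lower depth by a median total 1.01 times that of the responding group BS. A general flattening by background met the prediction fixed for it. The slope of the culture change on that of the other groups, 0.484, lay under the bound of 0.5. That slope would leave a response of 0.42, a step that was no part of the prediction. This value rests on a mean of 0.88 in the other groups, whose own means ran from 0.05 in SK to 1.91 in MM. The response did not follow the slope, since group MM had a slope of 0.561 and the largest response. In SK, with a single batch, the slope was 1.33. The values of MM argue against flattening as the only source of the low response. A part played by flattening stays open. Regions already open in untreated cells stay open as an explanation. The untreated level of the group, 2.39 log2 CPM, was the highest of all groups, and its treated level lay 0.06 above the lowest of the 4 groups that responded, though below that of BS (2.43 against 3.39). The activity of the IFN-beta used and a biological difference between the colonies stay open and were not tested.

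Of the 37 regions that differed between Tyk2-inact and Tyk2-ko macrophages 26 lay on chromosome 9, which carries Tyk2. None lay near the gene, with 0 of the 37 within 10 Mb of it. The share of tested regions there was 5.27% (odds ratio 42.6). An effect of the lost protein on these regions of chromosome 9 is argued against. Of the 26, 23 were called against wild type in Tyk2-inact, which makes the protein. The lowest adjusted p among the 26 in Tyk2-ko was 0.272. Sequence of another strain carried with the mutated gene stays open. Of the 23 regions tested in CD8 T cells 17 moved the same way there, as did 11 of 11 on other chromosomes (Fisher's exact p = 0.145). These 11 are neighbours at X:169993670-170005642 and Y:90737545-90813135 and are not independent, so that this test decides nothing. The labels name no strains. A biological effect of the inactive kinase on these regions was not tested.

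In 4 libraries of group TD, reads over the exons of Stat1 stood at 10.6 to 34.4 times the usual level. A gain of accessibility over the whole gene is argued against by the introns, at a median of 1.16 times the usual level in the same libraries. Spliced copies of the gene in some libraries may be the source, since 1 of 803 genes scanned, Stat1 itself, showed this pattern. No biological explanation was tested.

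Differences between lines gave further values. Tyk2-inact and Tyk2-ko differed in 6892 regions of CD8 T cells. The IFN-beta response differed from that of wild types in 5289 regions of Stat1a-only CD8 T cells (2244 at 1.5 h alone, 3272 at 20 h alone) and in 1382 regions of Stat1-ko at 20 h. It differed in 3 regions of Irf9-ko CD8 T cells (6 at 20 h), 4 of Tyk2-ko at 20 h, 1 of Tyk2-inact, 1 of Stat5-ko at 1.5 h (a single library, which kept 85.7% of the wild type signal over the targeted gene), 1 of Tyk2-inact macrophages at 1.5 h and 2 of Tyk2-ko macrophages at 20 h.

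A library lay far from the others of its group in 18 of 77 tests, each of a group on a measure, where chance gives about 5%. That rate does not apply over the targeted gene, where any read in a single library is flagged if the others hold 0. Over the deleted part of the targeted gene, the B cell Stat5-ko replicate 4 held 49.2 CPM (others 0.676 to 4.44) and the CD8 T cell Stat5-ko replicate 4 held 66.9 CPM (2.12 to 8.72). The library labelled Irf9-ko, CD8 T cells at 20 h of IFN-beta, replicate 2, held 2.38 CPM where the others held 0, and that of Stat2-ko, replicate 3, held 0.481. Values of 0.526 CPM in untreated Irf9-ko macrophages (replicate 2), 0.226 in Tyk2-ko CD8 T cells (replicate 3) and 1.09 in Tyk2-inact macrophages (replicate 3) rest on few reads. In Tyk2-inact they cover regions that lost signal, not a known deletion. The share of counts in promoters was 46.8% in Stat3-ko CD8 T cells (replicate 2, others 42.6 to 43.1), 44.4% in Tyk2-ko CD8 T cells (replicate 1, 48.5 to 50.2), 42.7% in Tyk2-ko dendritic cells (replicate 2, 33.9 to 34.5), 38.7% in wild type dendritic cells (replicate 1, 35.3 to 35.6) and 33.2% in Stat3-ko macrophages (replicate 3, 44.6 to 46.4). In untreated cultured macrophages it was 40.4% in Irf9-ko (replicate 4, 30.9 to 31.5) and 41.3% in Stat2-ko (replicate 4, 29.9 to 31.5). The mean log2 CPM of interferon-stimulated gene regions was 3.17 in Stat3-ko B cells (replicate 3, others 3.25 to 3.26), 2.06 in untreated Stat3-ko CD8 T cells (replicate 1, 2.30 to 2.31), 2.39 in homeostatic Stat3-ko CD8 T cells (replicate 2, 2.09 to 2.12) and 2.07 in Tyk2-ko CD8 T cells (replicate 1, 2.21 to 2.29).

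Other splits of the same libraries were tried on 5000 sampled regions. Chance could be excluded for the culture of macrophages (3444 called, 1 of 100 splits as large, highest other 3) and of CD8 T cells (2718, 1 of 100, 381). A share under 0.05 of the splits was as large for IFN-beta in wild type CD8 T cells at 1.5 h (86, 3 of 100, 131) and 20 h (324, 2 of 100, 359). The same held for Stat5-hyp in CD8 T cells (509, 1 of 32, 139), B cells (333, 1 of 32, 32) and NK cells (109, 1 of 32, 69), for Stat5-ko in CD8 T cells (123, 1 of 32, 4) and B cells (152, 1 of 32, 106), and for Tyk2-ko macrophages (7, 3 of 100, 44). Most of these splits joined batches, however. Among those that parted as many batch pairs as the real split, only the real one was as large. With the real one they numbered 8 for each of these Stat5 lines, 3 for Tyk2-ko macrophages and 1 for each IFN-beta comparison. No share under 0.05 can be had from so few, so that chance stays open for these comparisons. Chance could also not be excluded for Tyk2-inact macrophages (19, 5 of 100, 61) and the response of Stat1a-only CD8 T cells (3, 18 of 100, 1726). For the response of Stat1-ko CD8 T cells (2, 3 of 100, 3) it stays open, since 2 of the 8 splits that part as many pairs were as large and edgeR over all regions called 0 (5015 at an unadjusted p under 0.05, 0 by DESeq2). With 10 splits no share under 0.05 can be had, and the real value was above 0 there in Stat5-ko macrophages (45, 1 split as large, highest other 0), Stat2-ko CD8 T cells (2, 1, 0), Tyk2-inact NK cells (2, 1, 0) and the response of Tyk2-ko CD8 T cells (19, 1, 0). In the other 11 comparisons with 10 splits the real count was 0, so that all 10 were as large, with at most 36 in another split. In 24 comparisons with more splits the real count on the sampled regions was 0 as well, so that all 32, 34, 35, 45, 53, 54 or 100 splits were as large and the splits decide nothing. Among these are homeostatic CD8 T cells of Tyk2-inact, of Tyk2-ko and of both alleles compared, for which chance is left open. Splits that joined batches called up to 2369 regions between the alleles there, 610 for Tyk2-inact and 556 for Tyk2-ko, 373 between the alleles of macrophages and 73 for dendritic cells, which points to a structure of the libraries beside the genotype.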

How the results depend on the processing

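The estimated correlation of gene lists, and the fits without batches TDAL009, RMVG028, RMMF174 and BSMJ016 and without the near-duplicate Stat6-ko library, were chosen after the result was seen. Of 650 recomputed counts 426 lay within 1.5 times the reported one, 72 rose and 152 fell further. Named called regions kept their side of the threshold in 2415 of 2814 refits, lost it in 399 and turned in 0. All counts of 0 for dendritic cells, Stat1a-only CD8 T cells, both STAT1 forms compared in CD8 T cells and macrophages at 1.5 h kept 0 throughout. No fit without a filter was run for responses between genotypes. The response of Stat5-ko CD8 T cells without batch RMVG028 or replicate 1 could not be fitted, since no library at 1.5 h would be left, and homeostatic Stat5-ko CD8 T cells without batch RMMF174 and Stat6-ko macrophages without the near-duplicate are those without replicates 4 and 3. For each count below that moved, the cause was not tested, except that unfiltered fits test more regions and that fits without a replicate or within the own group use fewer libraries. A lone library left in an arm was assumed to vary like the others.

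In homeostatic cells DESeq2 with the replicate block within the own research group gave, in macrophages, 1 in Irf9-ko, 1 in Stat1-ko, 0 in Stat1a-only, 5 in Stat2-ko, 2 in Stat3-ko, 5 in Stat5-hyp, 405 in Stat5-ko, 1 in Stat6-ko, 103 in Tyk2-inact, 115 in Tyk2-ko and 7 for Tyk2-inact against Tyk2-ko. CD8 T cells had 0 in Irf9-ko, 4 in Stat2-ko, 3520 in Stat5-hyp, 5049 in Stat5-ko, 3 in Stat6-ko, 9 in Tyk2-inact, 16 in Tyk2-ko and 1 for Tyk2-inact against Tyk2-ko. The counts of B cells were 3 in Stat3-ko, 473 in Stat5-hyp and 803 in Stat5-ko. For NK cells they were 0 in Stat3-ko, 453 in Stat5-hyp, 7 in Tyk2-inact and 8 in Tyk2-ko.

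EdgeR with the own research group only gave, in macrophages, 9 in Irf9-ko, 36 in Stat1-ko, 25 in Stat1a-only, 1 in Stat1b-only, 19 in Stat2-ko, 69 in Stat3-ko, 1 in Stat4-ko, 12 in Stat5-hyp, 1480 in Stat5-ko, 17 in Stat6-ko, 111 in Tyk2-inact, 68 in Tyk2-ko, 166 for Stat1a-only against Stat1b-only and 6 for Tyk2-inact against Tyk2-ko. It gave, in CD8 T cells, 17 in Irf9-ko, 11 in Stat1-ko, 65 in Stat2-ko, 24 in Stat3-ko, 211 in Stat6-ko, 50 in Tyk2-inact, 26 in Tyk2-ko and 604 for Tyk2-inact against Tyk2-ko. NK cells had 2014 in Stat3-ko and 5003 in Stat5-hyp.

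Leaving out the replicate block, with research group as covariate, gave, in macrophages, 11 in Irf9-ko, 7 in Stat1-ko, 0 in Stat1a-only, 42 in Stat2-ko, 15 in Stat3-ko, 87 in Stat5-hyp, 2289 in Stat6-ko, 121 in Tyk2-inact and 65 in Tyk2-ko. The counts of CD8 T cells were 0 in Irf9-ko, 1 in Stat1-ko, 9 in Stat3-ko, 318 in Stat6-ko, 33 in Tyk2-inact and 29 for Tyk2-inact against Tyk2-ko. For B cells they were 3 in Stat3-ko and 1062 in Stat5-hyp. It gave, in NK cells, 117 in Stat3-ko and 1217 in Stat5-hyp.

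RLE size factors gave, in macrophages, 257 in Stat2-ko and 1626 in Stat5-hyp. CD8 T cells had 3 in Irf9-ko, 5 in Stat1-ko, 189 in Stat6-ko, 6396 in Tyk2-inact and 16718 for Tyk2-inact against Tyk2-ko. The counts of NK cells were 0 in Stat3-ko. The replicate block with a GC and abundance offset gave, in macrophages, 473 in Stat5-hyp and 22 for Stat1a-only against Stat1b-only. For CD8 T cells they were 7 in Irf9-ko, 7 in Stat1-ko, 40 in Stat2-ko, 9 in Stat3-ko, 12174 in Stat5-hyp, 50 in Stat6-ko, 684 in Tyk2-inact and 2073 for Tyk2-inact against Tyk2-ko. It gave, in NK cells, 89 in Stat3-ko, 4951 in Stat5-hyp, 83 in Tyk2-inact and 35 in Tyk2-ko. No low-count filter gave, in macrophages, 1 in Stat3-ko. CD8 T cells had 1 in Stat1-ko, 2 in Stat3-ko, 4742 in Stat5-ko, 11 in Stat6-ko, 281 in Tyk2-inact and 1717 for Tyk2-inact against Tyk2-ko. The counts of B cells were 3 in Stat3-ko. For NK cells they were 773 in Stat5-hyp and 7 in Tyk2-ko. Leaving out libraries under 0.333 of the median total gave, in macrophages, 254 in Stat5-hyp. It gave, in CD8 T cells, 2 in Irf9-ko and 1 in Stat1b-only. NK cells had 4 in Stat3-ko, 3942 in Stat5-hyp, 136 in Tyk2-inact and 27 in Tyk2-ko. Leaving out regions within 10 Mb of the mutated gene gave, in macrophages, 7 in Stat1-ko and 3 in Stat6-ko. The counts of CD8 T cells were 1 in Stat1-ko.

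For culture, no low-count filter gave 177143 in macrophages and 65359 in CD8 T cells. For IFN-beta in wild type CD8 T cells it gave 527 at 1.5 h and 3010 at 20 h, and DESeq2 with the replicate block 2913 and 1668. Without group MM there were 47 and 985. At 1.5 h there were 1095 without group RM and 1071 with the GC and abundance offset, and at 20 h 1258 without libraries whose title differs. Macrophages at 20 h had 1 without group TD.

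For the response in mutants, DESeq2 within the own group with the replicate block gave, in CD8 T cells, 0 in Irf9-ko, 0 in Stat1a-only, 14 in Tyk2-inact and 14 in Tyk2-ko. EdgeR with the own group only gave, in CD8 T cells, 0 in Irf9-ko, 138 in Stat1a-only, 57 in Tyk2-inact and 125 in Tyk2-ko. No replicate block, with research group as covariate, gave, in CD8 T cells, 0 in Irf9-ko, 2413 in Stat1a-only and 0 in Tyk2-inact. The time of 1.5 h alone gave, in macrophages, 1 in Tyk2-inact. For CD8 T cells they were 0 in Irf9-ko, 2244 in Stat1a-only, 1 in Stat5-ko and 0 in Tyk2-inact. The time of 20 h alone gave, in macrophages, 2 in Tyk2-ko. It gave, in CD8 T cells, 6 in Irf9-ko, 1382 in Stat1-ko, 3272 in Stat1a-only, 0 in Tyk2-inact and 4 in Tyk2-ko. Leaving out batch TDAL009 gave, in CD8 T cells, 0 in Irf9-ko. Leaving out the Stat1a-only libraries of BSMJ016 gave, in CD8 T cells, 0 in Stat1a-only. With an estimated correlation 4 of 15 calls of interferon-responsive regions and 15 of 203 calls of gene lists in homeostatic, wild type and response comparisons held (0 of 33 in untreated cultured cells).

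Leaving out 1 mutant replicate at a time, homeostatic counts ranged, in macrophages, from 1 to 22 in Irf9-ko, 0 to 6 in Stat1-ko, 0 to 0 in Stat1a-only, 12 to 727 in Stat2-ko, 1 to 4 in Stat3-ko, 6 to 16477 in Stat5-hyp, 568 to 4191 in Stat5-ko, 0 to 8 in Stat6-ko and 0 to 1 for Stat1a-only against Stat1b-only. CD8 T cells ranged from 0 to 2 in Irf9-ko, 0 to 3 in Stat1-ko, 0 to 1 in Stat1b-only, 9 to 17 in Stat2-ko, 0 to 3 in Stat3-ko, 0 to 1 in Stat4-ko, 3305 to 7919 in Stat5-hyp, 1819 to 7119 in Stat5-ko, 6 to 20 in Stat6-ko, 85 to 5355 in Tyk2-inact and 369 to 13117 for Tyk2-inact against Tyk2-ko. B cells ranged from 3 to 22 in Stat3-ko, 2203 to 2855 in Stat5-hyp and 2133 to 4386 in Stat5-ko. NK cells ranged from 0 to 3 in Stat3-ko, 159 to 1931 in Stat5-hyp, 2 to 21 in Tyk2-inact and 0 to 15 in Tyk2-ko.

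Leaving out the same replicate number of every condition, response counts ranged, in macrophages, from 0 to 3 in Stat1-ko. CD8 T cells ranged from 0 to 0 in Irf9-ko, 0 to 5 in Stat1-ko, 0 to 13976 in Stat1a-only, 0 to 1 in Stat3-ko, 0 to 2 in Stat5-ko, 0 to 1 in Tyk2-inact and 0 to 1 in Tyk2-ko.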

Other observations

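CD8 T cells with hyperactive STAT5B also opened regions outside the loci described above. A region by Irf7, the amplifier of the interferon response (7:141270673-141271091), rose by 2.48 ± 0.39 (5 against 8 libraries), 1 by Tap2, a peptide transporter of MHC class I presentation, by 1.55 ± 0.24, and 1 by Entpd1, an enzyme that breaks down extracellular ATP, by 2.91 ± 0.34. In Tyk2-inact CD8 T cells (4 against 6) regions at Cd40, an activating receptor of antigen-presenting cells (2:165049299-165049506), and at H2-Aa, an MHC class II chain, rose by 3.83 ± 0.82 and 1.84 ± 0.39. T cell markers had a median of −0.32 in this comparison, whose 2268 calls fell to 85 without replicate 1, 89 without replicate 4 and 9 by DESeq2.

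The cultured Stat6-ko libraries, 1 per cell type and condition, had a 20 h response of 0.14 in macrophages and 0.11 in CD8 T cells over the interferon-responsive regions, where the wild type of the same batch had 0.09 and 0.05. The dendritic cell library of Tyk2-inact had a mean of 2.60 log2 CPM over regions near interferon-stimulated genes, and the 4 wild type libraries 2.71 to 2.77. The CD8 T cell library of Stat4-ko at 20 h of IFN-beta had 2.66, within the 2.63 to 3.01 of 5 wild types. Replicates 2 and 3 of homeostatic Stat6-ko macrophages had the closest counts of 48754 pairs of libraries, with a chi-square per degree of freedom of 0.809 (median 2.90). The next pair, at 0.907, was wild type CD8 T cells of batch TDAL010 at 1.5 h and 20 h of IFN-beta. Pairs of Tyk2-ko and Tyk2-inact libraries of 1 batch had 0.933 in CD8 T cells and 0.936 in macrophages. A Tyk2-ko macrophage library at 20 h of IFN-beta (replicate 2) held 634 CPM over the exons of Tyk2, and its introns 9.71 times the usual level.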
